A study of Mus musculus with 4 samples.

How the data were processed

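RNA from cultures of EO771, a mouse mammary carcinoma cell line, was hybridised to 4 single-colour expression arrays after biotin labelling. Per the labels' protocols, cells were cultured for 24 hours to at least 70% confluence and then received recombinant mouse adipose fatty acid binding protein (A-FABP, the product of Fabp4) at 100 ng/ml. The series design names PBS as the control. The length of the treatment is not given in the sources used here. The titles call the arrays biological replicates, 2 per group, and groups were taken from the titles. The free-text description of the control arrays also names A-FABP treatment, whereas their titles, source names and the series design mark them as controls.

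The deposited table holds 1 log2 expression value per probe set and array, as the authors made it. The submitters' processing notes name RMA, a method that corrects background, normalizes between arrays and summarises probes, and Partek 6.6. The array design, the probe set definition and the genome build are not given in the sources used here, so no coordinates are printed. The labelling protocol names an Affymetrix 3' kit, and whether it fits the array design was not settled, so which part of a transcript a probe set reads is left open. RMA shrinks differences near the background and near the brightest values, so fold changes of very dim and very bright probe sets are understated. Background flags and probe-level intensities were not used here, so detection was not called. For arrays, the number of arrays limits the precision. Probe set identifiers are numeric and unlabelled as controls, so the planned comparison of 3' and 5' control probe sets, a check of RNA integrity, was not possible and control probe sets could not be left out.

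The annotation of the platform named 1 gene for 23521 of the 41345 probe sets and several genes for 1814. The other 16010 have no gene in it and are unnamed here. Of all rows, 808 repeat the 4 values of an earlier row. For 1082 genes with more than 1 probe set, the gene is represented by the one with the highest mean over all 4 arrays, which gave 22180 genes. A probe set with several genes names none.

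Differences are A-FABP minus PBS control on the log2 scale, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over all 41345 probe sets, with two-sided p-values and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. The fit has 2 residual and 1.91 prior degrees of freedom. SE and 95% confidence intervals come from this fit. An exact permutation test of a single gene with 2 arrays against 2 cannot give a two-sided p below 0.33. A looser list (at least 1.5-fold and unadjusted p under 0.05) is given as a description. The 28 gene lists were fixed before the data were examined, from the cell type, the treatment and the assumed topics of the study. Those topics were IL-6, STAT3, aldehyde dehydrogenases and stemness. The lists cover signalling, stemness, metabolism, proliferation and stress as well as markers of leukocytes, fibroblasts, endothelial cells and adipocytes. They were tested with limma's camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene, with Benjamini-Hochberg adjustment over the lists. Symbols in the lists that the annotation does not use were matched through RefSeq synonyms (assembly GRCm38.p6, used for names only) where the match was unique. Through such synonyms Pigq stood for Gpi1 in the glycolysis list and Loxl3 for Loxl2 in the mesenchymal list. These are different genes, so both lists differ in a member from those fixed beforehand. Because differences followed the mean level of a probe set, each list's median was also set against 10000 random lists matched on mean level in 50 bins.

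Genes named in the text as results follow a rule fixed before the data were examined, except Adipoq and Lep, which were chosen outside it. In each direction it takes up to 10 genes whose arrays do not overlap, whose higher group mean lies above the median of all probe sets and which pass the adjusted threshold. Where fewer pass, it is filled with the lowest unadjusted p among genes changed at least 1.5-fold. It adds a fixed panel of 14 genes and up to 4 members of each list with the lowest p. In use, 4 members were taken for lists past the threshold and 2 for the rest, a split chosen after the calls were known.

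The fit was tested on simulated data with the means of the real probe sets and the fitted distribution of variances. Of 66 probe sets changed by 2 on the log2 scale, 0 passed the adjusted threshold and 98.5% had an unadjusted p under 0.05. At a true difference of 1, the numbers were 0 of 67 and 89.6%. At a true difference of 0.585, close to 1.5-fold, they were 0 of 67 and 94.0%. The simulation changed only these few of the 41345 probe sets, whereas 73.8% of the real ones were estimated to be unchanged (limma's propTrueNull), so it does not give the reach of the adjusted threshold in these data. In simulated lists of 25 genes with independent errors, camera called 20 of 20 lists shifted by 0.2 and 0 of 80 unshifted lists. In the real lists, the estimated inter-gene correlation was 0.705 for G2/M phase genes and 0.105 for NF-kB targets. It was -0.029 to -0.018 for cholesterol synthesis, S phase and TGF-beta and Wnt targets. Simulated lists with independent errors therefore do not give the rate of false calls in these data.

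Alternatives fixed before the data were examined were the replicate number as a block, median centring, cyclic loess and repeated quantile normalization between arrays, 2 filters on dim probe sets, eBayes with trend and robust settings, no variance moderation, the mean over a gene's probe sets, looser and stricter thresholds, camera with an estimated correlation, fry, and leaving out each array in turn. Leaving out an array leaves 1 array in its group, whose spread is assumed to equal that of the other group. Added after seeing the data were a fit on probe sets with 1 gene, a fit with identical rows counted once, and removal of the trend of the difference on mean level (loess, span 0.2). The replicate numbers were checked as pairs: the difference between replicates 1 and 2 in the A-FABP group and in the control group correlated at r = -0.009 across probe sets, and with 2 pairs and no label of a shared day the samples were treated as unpaired.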

Results

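Gene expression was measured in EO771 mouse mammary carcinoma cells cultured with recombinant A-FABP at 100 ng/ml (2 arrays) or with PBS (2 arrays). A-FABP, encoded by Fabp4, is a lipid chaperone of adipocytes and macrophages that also circulates in blood. The comparison asks which transcripts of the carcinoma cells differ after exposure to the extracellular protein. The 4 arrays had median log2 values of 5.98 and 5.95 with A-FABP and 6.03 in both controls. Replicates correlated across 41345 probe sets at r = 0.9906 with A-FABP and r = 0.9914 with PBS, and arrays of different groups at r = 0.9853 to 0.9889. The SD of the difference between 2 arrays was 0.320 within the A-FABP group, 0.303 within the control group and 0.345 to 0.397 between groups.

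Genes named by a fixed rule included NF-kB feedback genes on the lower side and zinc finger genes on the higher side. Gadd45b, a growth arrest and DNA damage gene, was 2.40-fold lower (log2 difference -1.27 ± 0.18 SE, 2 arrays per group), at 9.96 ± 0.31 (SD) against 11.23 ± 0.07. Its relative Gadd45g lay at -0.88 ± 0.11, and Tnfaip3, which encodes the NF-kB inhibitor A20, at -0.88 ± 0.16. Nfkbia, which encodes the NF-kB inhibitor IκBα, lay at -0.69 ± 0.11. In these 4 genes both A-FABP arrays lay below both controls, which the rule required of Gadd45b, Gadd45g and Nfkbia. Groups that do not overlap, in one order or the other, were found in 53.5% of all genes. Zfp97, a zinc finger gene, was 3.03-fold higher (1.60 ± 0.11), at 6.73 ± 0.01 (SD) against 5.13 ± 0.15. No probe set passed the adjusted threshold: the lowest limma adjusted p was 0.296, and 0 of 41345 probe sets were called. Because 0 passed, the genes below are given as values and not as calls. At an unadjusted p under 0.05 there were 6258 probe sets, unnamed ones included, where 2067 are expected with no effect.

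**Figure D1:**
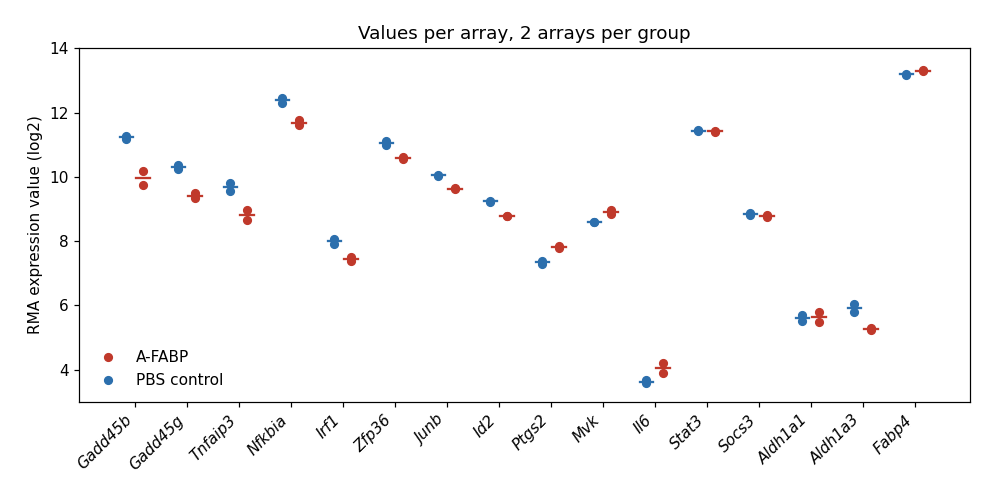
RMA expression values (log2, vertical axis) of 16 genes on each of the 4 arrays, with A-FABP in red and PBS control in blue; points are arrays and short lines are group means of 2 arrays. Gadd45b, Gadd45g, Tnfaip3 and Nfkbia lay lower on both A-FABP arrays than on both controls, while Stat3 differed by -0.02. Arrays that do not overlap were a condition for selecting Gadd45b, Gadd45g and Nfkbia.

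Among 22180 genes, 235 differed at least 1.5-fold at an unadjusted p under 0.05, 92 higher and 143 lower with A-FABP. The other 2 splits of the 4 arrays into 2 and 2 gave 60 and 83 such genes. In those splits a difference between A-FABP and PBS counts as spread, which lowers their counts. They gave 343 and 336 genes at an unadjusted p under 0.05, where 1109 are expected with no effect. They are therefore no baseline for the 235 genes. Both arrays of one group lay above both of the other in 53.5% of genes, where chance gives 33.3%. The balance between higher and lower genes depended on the scaling. It was 92 to 143 as deposited, 157 to 68 after median centring, 138 to 64 after cyclic loess and 95 to 110 after repeated quantile normalization.

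On the higher side, 4 of the 10 genes selected by rule were zinc finger genes. Beside Zfp97, Zfp975 lay at 1.11 ± 0.10, Zfp985 at 0.84 ± 0.11 and Zfp935 at 0.81 ± 0.09. Genes of this family have close paralogs, and signal shared between copies was not tested. The other genes were A630089N07Rik (0.99), Mylpf, a fast skeletal myosin light chain (0.92), Otud7a, a deubiquitinase (0.80), Krt23, a keratin (0.70), Ly6c2, a surface antigen of monocytes (0.67), and Tnfsf18, a TNF family ligand (0.63). On the lower side, beside Gadd45b, Gadd45g and Nfkbia, stood the microRNA genes Mir494 (-0.93), Mir1945 (-0.60) and Mir5112 (-0.59). Muc3a, a mucin (-0.73), Prlh, which encodes prolactin-releasing hormone (-0.63), Lingo1 (-0.62) and Clpsl2 (-0.59) completed it. Several of these genes lay near the array medians of 5.95 to 6.03. With A-FABP against PBS, Muc3a lay at 5.40 against 6.13, Lingo1 at 5.57 against 6.19 and Mylpf at 6.16 against 5.24. Genes at levels of 5 to 6 and 6 to 7 had median differences of -0.146 and -0.101. Gadd45g (9.42 against 10.30) and Nfkbia (11.69 against 12.38) were brighter. The limma adjusted p was 0.296 for each of these 20 genes, and unadjusted values ran from 0.000136 for Zfp97 to 0.00327 for Nfkbia.

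As a set, NF-kB inflammatory targets fell at the preset correlation, a call not given by an estimated correlation or by fry. Of 27 measured members, 21 lay below 0 and 6 above, with a median log2 difference of -0.17 (quartiles -0.33 and -0.05), against 0.03 for random lists of the same brightness and -0.10 after median centring. Camera gave an adjusted p of 0.00228 at the preset correlation, and adjusted p = 0.669 with an estimated correlation. Fry gave an adjusted p of 0.256. At an unadjusted p under 0.05, 8 members were lower and 1 higher, where 1828 of all 22180 genes were lower and 1066 higher. Adjusted over all probe sets 0 members passed, and adjusted over the list alone 4 did. Nfkbia, Tnfaip3 and Irf1 (-0.55 ± 0.11), an interferon-responsive transcription factor, were the lower ones. Ptgs2, which encodes the prostaglandin synthase COX-2, was the higher one at 0.48 ± 0.09. Nfkbia and Tnfaip3 are NF-kB targets whose products restrain the pathway. Macrophage and pan-leukocyte markers, which were dim and did not pass, had a median of -0.21, against -0.11 for random lists of their brightness.

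TGF-beta and Wnt targets also fell as a set at the preset correlation, but were not called with an estimated correlation or with fry (fry adjusted p = 0.155). Of 26 members 19 lay below 0, the median was -0.20 (quartiles -0.35 and 0.00) and the camera adjusted p was 0.00786, with adjusted p = 0.656 with an estimated correlation. Id2, an inhibitor of basic helix-loop-helix factors, lay at -0.47 ± 0.08, and Lef1, a transcription factor of the Wnt pathway, at -0.54 ± 0.10. Lef1 lay below the array medians, at 5.45 with A-FABP against 5.99 with PBS. Axin2 (-0.37 ± 0.09, and -0.21 at its other probe set) and Rnf43 (-0.32 ± 0.08) are feedback inhibitors of Wnt signalling. At an unadjusted p under 0.05, 8 members were lower and 1 higher, where 1828 of all 22180 genes were lower and 1066 higher. No member passed adjusted over all probe sets or over the list alone. Brightness-matched random lists had a median of -0.01, and the list's own median was -0.13 after median centring.

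Cholesterol synthesis genes rose as a set, by a small amount, at the preset correlation, a call not given by an estimated correlation or by fry. Of 19 measured members 18 lay above 0, with a median of 0.13 (quartiles 0.09 and 0.17), against 0.03 for brightness-matched lists and 0.20 after median centring. In 14 of the 19, both A-FABP arrays lay above both controls, and in 0 below. The groups did not overlap, in one order or the other, in 53.5% of all genes, where chance gives 33.3% for both orders together. Mvk, which encodes mevalonate kinase, lay at 0.33 ± 0.09 and the sterol carrier gene Stard4 at 0.23 ± 0.08. Lss, which encodes lanosterol synthase, lay at 0.18 ± 0.08 and Hmgcs1, an early enzyme of the pathway, at 0.17 ± 0.08. The camera adjusted p was 0.00151, and adjusted p = 0.656 with an estimated correlation. Fry gave an adjusted p of 0.155. At an unadjusted p under 0.05, 2 members were higher, as were 1066 of all 22180 genes. No member passed adjusted over all probe sets or over the list alone.

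Both proliferation lists rose as sets at the preset correlation. S phase and DNA replication genes had a median of 0.08, with 21 of 24 above 0, and G2/M phase genes of 0.10, with 22 of 26 above 0. Camera adjusted p-values were 0.00574 and 0.00489, and with an estimated correlation adjusted p = 0.656 and adjusted p = 0.913. Fry gave adjusted p-values of 0.155 and 0.364. The leading S phase members were Tyms, which encodes thymidylate synthase (0.38 ± 0.10), Gins1 (0.17), Rrm2 (0.17) and Slbp (0.17). The other Rrm2 probe set, dim at 4.39 with A-FABP against 4.13 with PBS, lay at 0.26 ± 0.26 with overlapping groups. The leading G2/M members were the kinetochore motor gene Cenpe (0.26 ± 0.09), the proliferation marker Mki67 (0.20), Cenpf (0.19) and Kif20a (0.17). At an unadjusted p under 0.05, 1 member of each list was higher, as were 1066 of all 22180 genes, so these counts do not set the lists apart. No member passed adjusted over all probe sets or over the list alone. Brightness-matched random lists had medians of 0.07 and 0.05, and the lists' own medians were 0.15 and 0.16 after median centring. Without A-FABP replicate 1 the medians were 0.07 and 0.04 and the camera adjusted p-values 0.0797 and 0.461. After cyclic loess the medians were 0.02 and 0.05 and neither list was called (adjusted p = 0.494 and 0.358). Over all alternatives the adjusted p ranged from 0.00189 to 0.656 for S phase and from 3.74e-05 to 0.913 for G2/M.

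**Figure D2:**
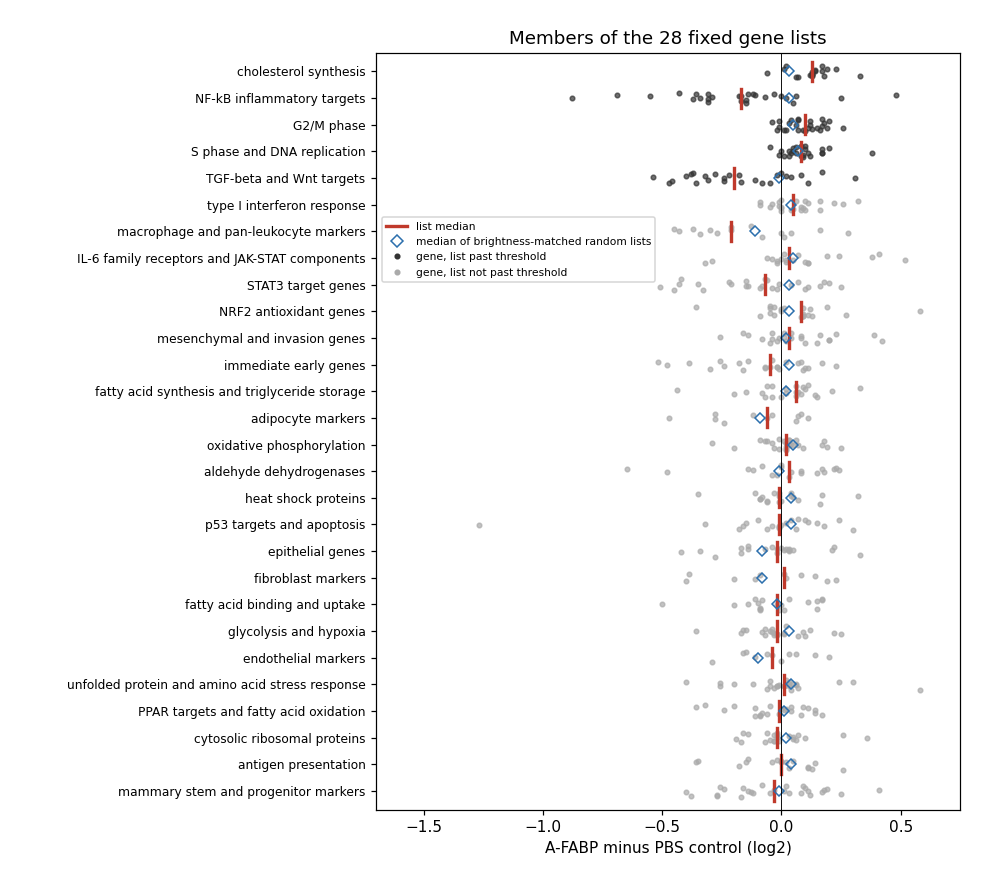
Log2 difference, A-FABP minus PBS control (horizontal axis), of the measured members of 28 gene lists, ordered by camera p-value from the top; points are genes, red lines list medians and blue diamonds the median of brightness-matched random lists. Dark points mark the 5 lists with an adjusted p under 0.05 at the preset correlation: cholesterol synthesis, G2/M phase and S phase to the right, NF-kB and TGF-beta and Wnt targets to the left. With an estimated correlation 0 lists passed, and with fry 0.

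A panel fixed before the data were examined covered IL-6 and STAT3 signalling, aldehyde dehydrogenases and stemness. That the study concerns these topics was assumed when the panel and the gene lists were fixed. Il6, which encodes the cytokine, lay at 0.41 ± 0.14 (95% CI 0.01 to 0.80), at 3.88 and 4.19 with A-FABP and 3.68 and 3.57 with PBS, all dim values (limma adjusted p = 0.325). The Il6 difference was 0.25 without A-FABP replicate 2. Stat3 lay at -0.02 (95% CI -0.24 to 0.19) and the receptor genes Il6ra at 0.01 (-0.20 to 0.23) and Il6st at 0.05 (-0.18 to 0.28). The sign of Il6ra turned to -0.03 under cyclic loess and repeated quantile normalization and to -0.02 with the trend on mean level removed. Socs3, the feedback inhibitor induced by STAT3, lay at -0.07 (-0.31 to 0.17), and its other probe set at 0.05. Within the IL-6 family and JAK-STAT list (median 0.03, camera adjusted p = 0.122), the cytokine gene Il11 lay at 0.52 ± 0.13 and the oncostatin M receptor gene Osmr at 0.38 ± 0.10. STAT3 target genes had a median of -0.07, with 18 of 26 below 0 (camera adjusted p = 0.204, and adjusted p = 0.669 with an estimated correlation). Brightness-matched lists had a median of 0.03, and the STAT3 list lay at percentile 0.02 of them. Their leading members were the AP-1 gene Junb (-0.43 ± 0.08) and the kinase gene Pim1 (-0.42 ± 0.10, and -0.18 at its other probe set). The STAT3 list was called as lower after cyclic loess (adjusted p = 0.0376), with the filter at the median level (0.00221) and with trend and robust settings (0.0165).

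Aldehyde dehydrogenases had a list median of 0.03 over 19 genes, a mean of -0.01, and a camera direction of up with an adjusted p of 0.836. Aldh1a1 lay at 0.03 (95% CI -0.40 to 0.47) and Aldh3a1 at 0.00 (-0.36 to 0.37), and the signs of both turned with an array left out. Aldh1a3 lay at -0.65 ± 0.12 and Aldh1b1 at -0.48 ± 0.08, and in both genes the A-FABP arrays lay below the controls (limma adjusted p = 0.296). Their group means were 5.27 against 5.91 and 6.02 against 6.50, on arrays with medians of 5.95 to 6.03. Genes at mean levels of 5 to 6 and 6 to 7 had median differences of -0.146 and -0.101. Mammary stem and progenitor markers had a median of -0.03 over 27 genes (camera adjusted p = 0.957). Among them, Id1 lay at -0.38 ± 0.08, the drug efflux transporter gene Abcg2 at 0.25 ± 0.08 and Cd44 at 0.12 (95% CI -0.09 to 0.34). Myc lay at -0.21 (-0.42 to 0.01) and Ccnd1, which encodes cyclin D1, at 0.10 (-0.14 to 0.34).

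Fabp4 was bright on all arrays, at 13.33 and 13.29 with A-FABP and 13.20 and 13.18 with PBS, a difference of 0.11 (95% CI -0.10 to 0.33). Fabp5 lay at -0.14 (-0.53 to 0.26; 0.02 without A-FABP replicate 1) and the nuclear receptor gene Pparg at -0.32 (-1.0 to 0.36; -0.02 without PBS control replicate 2). Fatty acid binding and uptake genes had a median of -0.02 over 19 genes, with Fabp2 at -0.50 ± 0.08 and Acsl5 at 0.17. Fabp2 was dim, at 4.70 with A-FABP against 5.20 with PBS. PPAR targets and fatty acid oxidation genes had a median of -0.01 over 23, with Pdk4 at -0.36 ± 0.18 (-0.18 without A-FABP replicate 2) and Etfdh at 0.17 (0.10 without PBS control replicate 2). Fatty acid synthesis and triglyceride storage genes had a median of 0.06 over 23, with Dgat2 at -0.44 ± 0.10 and Acacb at 0.33 ± 0.10. The camera adjusted p-values of these 3 lists were 0.946, 0.957 and 0.414.

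The remaining lists did not pass either. Immediate early genes had a median of -0.05 over 24 members (camera adjusted p = 0.324), against 0.03 for brightness-matched lists (percentile 0.04). Zfp36, which encodes an mRNA decay factor (-0.48 ± 0.09), and Fos (-0.52 ± 0.15) led them. Type I interferon response genes had a median of 0.05 over 24 (0.0896), led by Parp14 (0.32) and Irf7 (0.22). NRF2 antioxidant genes had a median of 0.08 over 21 (0.207). Their leading members went opposite ways, with the cystine transporter gene Slc7a11 at 0.58 ± 0.14 and Hmox1, which encodes heme oxygenase, at -0.36 ± 0.10. The other Slc7a11 probe set, dim at 3.76 with A-FABP against 3.71 with PBS, lay at 0.05. Mesenchymal and invasion genes had a median of 0.03 over 24 (0.240), with the matrix protease gene Mmp3 at 0.42 ± 0.11 and Col1a2 at -0.26. The other Col1a2 probe set, dim at 4.33 with A-FABP against 4.17 with PBS, lay at 0.17. Epithelial genes had a median of -0.02 over 21 (0.946), with Prss8 at -0.34 and Ocln at 0.33.

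Glycolysis and hypoxia genes (median -0.02), oxidative phosphorylation genes (0.02), cytosolic ribosomal proteins (-0.02), the unfolded protein and amino acid stress response (0.01), heat shock proteins (-0.01), p53 targets and apoptosis (-0.01) and antigen presentation (0.00) had camera adjusted p-values between 0.527 and 0.957. For ribosomal proteins, heat shock proteins and p53 targets, camera pointed up although the median lay below 0, and for p53 targets the mean was -0.05. Antigen presentation had a mean of -0.02 and a camera direction of up. Glycolysis and hypoxia genes lay at percentile 0.34 of brightness-matched lists, whose median was 0.03. The leading members of these lists were Adm (-0.36) and Aldoc (0.22), Ndufb8 (0.25) and Ndufs1 (0.19), Rpl27a (0.36) and Rpl11 (0.26), Slc7a11 and Ddit4 (-0.40), Chordc1 (0.32) and Hsph1 (0.17), Gadd45b and Apaf1 (0.30), and H2-Aa (-0.35) and Erap1 (0.26), in the order of the lists. Adjusted over the list alone, Gadd45b passed (0.0491) among p53 targets, and no member of the lists in this and the preceding paragraph did otherwise.

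Markers of other cell types did not pass as sets, and their members had median levels of 5.71 to 6.14 per list. Macrophage and pan-leukocyte markers had a median of -0.21 over 15 genes, against -0.11 for brightness-matched lists (camera adjusted p = 0.0896), with Itgam at -0.34 and Ptprc at -0.45. Adipocyte markers had a median of -0.06 over 11 (0.507), with Cidea at -0.47 and Cebpa at -0.28. Fibroblast markers had a median of 0.01 and a mean of -0.05 with a camera direction of down over 11 (0.946), with Mfap5 at -0.39 ± 0.09 and Thy1 at -0.40 ± 0.23 (-0.09 without A-FABP replicate 2). Endothelial markers had a median of -0.04 over 11 (0.946), with Tie1 at -0.29 and Eng at 0.20.

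Differences followed the mean level of a gene. Genes with a mean between 5 and 7 had a median of -0.13 and genes between 7 and 9 a median of 0.09, while the median over all genes was -0.01. The lowest interval median was -0.146 at levels of 5 to 6, over 4885 genes, and the highest was 0.092 at levels of 8 to 9, over 2435 genes. The medians did not rise steadily with level, with 0.065 below a level of 3 and 0.012 above 11. The shifts of the 5 called lists are therefore given beside the median of brightness-matched lists.

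**Figure D3:**
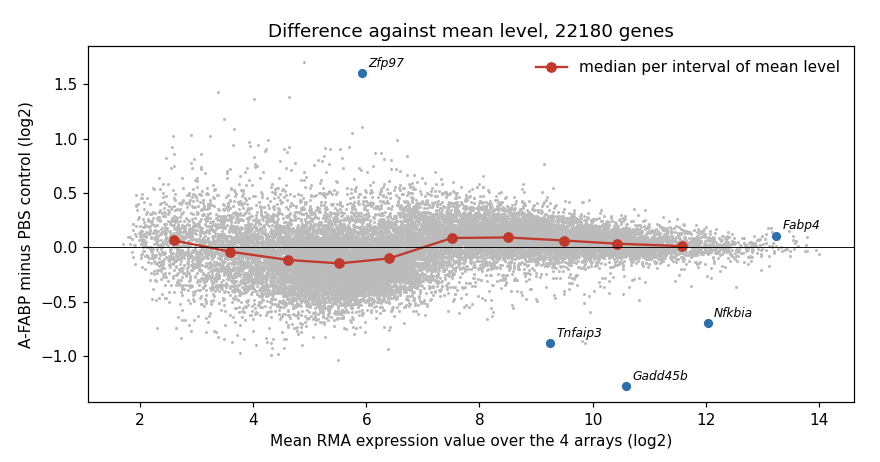
Log2 difference, A-FABP minus PBS control (vertical axis), against the mean RMA value over the 4 arrays (log2, horizontal axis) for 22180 genes in grey, with medians per interval of mean level in red and 5 named genes in blue. Medians ran from -0.146 at levels of 5 to 6 to 0.092 at levels of 8 to 9, and Gadd45b, Tnfaip3 and Nfkbia lay at -1.27, -0.88 and -0.69.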

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

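Fits on probe sets with 1 gene, with identical rows counted once and with the trend on mean level removed were chosen after seeing the data. Under the alternatives run, 0 probe sets and 0 genes passed the limma adjusted threshold, with lowest adjusted p-values of 0.156 to 0.579 and 3489 to 6876 probe sets at an unadjusted p under 0.05. The replicate block gave 0 probe sets, 0 genes, 230 genes past 1.5-fold and 5 lists, so it moved no count past 1.5 times. The 235 genes past 1.5-fold became 42 and 135 with the filters at the median and the 25th percentile of level, which test fewer genes, 112 without variance moderation and 14 at 2-fold (12 higher, 2 lower). With 1 array left out they numbered 314 to 591: 591 without A-FABP replicate 1, 365 without A-FABP replicate 2 and 457 without PBS control replicate 1, from fewer arrays. The 5 called lists became 0 with an estimated correlation and 0 with fry (lowest adjusted p 0.656 and 0.155), 3 with repeated quantile normalization and 3 with the trend removed. With 1 array left out they numbered 3 to 7, the lowest without A-FABP replicate 1. NF-kB, cholesterol synthesis and TGF-beta and Wnt targets stayed called under 14 of 16 alternatives, all except fry and the estimated correlation. Those 14 all kept camera at the preset correlation of 0.01, so they do not test that assumption. The calls ended under both alternatives that drop it, which also rest on a fit with 2 residual degrees of freedom. For cholesterol synthesis and TGF-beta and Wnt targets the estimated correlations, -0.029 and -0.018, lay below the preset one. A correlation above the preset is therefore not why these 2 lists lost their calls with an estimated correlation. For NF-kB targets the estimate was 0.105. Why the calls ended was not tested further. Median centring, which adds 1 amount per array to all probe sets, moved the median of all genes from -0.01 to 0.055 and the list medians with it. S phase stayed called under 9 and G2/M under 8. Both lost their call with lower medians under cyclic loess, repeated quantile normalization and the trend removed (S phase 0.02 to 0.03, G2/M 0.05, from 0.08 and 0.10) and without A-FABP replicate 1 (0.07 and 0.04). Both lost it with the same medians under the median filter, which tests fewer genes, and G2/M also without variance moderation (adjusted p = 0.454). The cause was not tested for the scalings and the moderation. Of 366 values recomputed for lists not called as deposited, 11 passed: STAT3 targets 3 times, interferon response 3 times, immediate early genes 2 times, leukocyte markers 2 times and IL-6 and JAK-STAT components 1 time. The camera direction of these lists turned in 75 of the 366, and the sign of named genes in 9 of 1509, in Stat3 (by that same shift), Il6ra, Fabp5, Aldh1a1 and Aldh3a1. With 1 array left out, 16 of 96 named genes moved by over 1.5 times: these 5 and Il6, Il6st, Socs3, Ccnd1, Pparg, Pdk4, Thy1, H2-Aa, Cenpf, Rpl11 and Etfdh. The SD of the difference between A-FABP replicates was 0.204 among probe sets above the median level and 0.320 over all, so dim probe sets limit the precision.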

Other observations

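Fabp4, the gene of the protein added to the cultures, gave values of 13.18 to 13.33 on the 4 arrays, whose medians were 5.95 to 6.03. A single probe set stands for the gene, and its brightness includes probe affinity. The adipocyte genes Adipoq and Lep, chosen outside the rule for named genes, had group means of 5.19 and 5.06 with A-FABP and 5.11 and 4.99 with PBS. The median level over the adipocyte list was 6.14.

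The patterns below were found in these data. The tests of the gene lists, the Zfp genes and the unnamed probe sets were set up after their medians and the trend on mean level had been seen, and the condition on the level of the receptor genes was added after their value was seen. The first pattern is that trend, a gap of 0.215 between the medians of genes at levels 7 to 9 and 5 to 7. The gap between replicates was at most 0.093 in size, below the bound set beforehand for contrast between any 2 arrays. Only 1 pair of replicates per group was compared, so contrast that varies between arrays and falls along the groups by chance is not excluded. With any array left out the gap between groups was at least 0.160 (without A-FABP replicate 2), which argues against 1 outlying array. Background that differed between the groups stays open: 1449 olfactory, vomeronasal, taste and trace amine receptor genes, not expected to be used by such cells, had a median of -0.03 against -0.05 for brightness-matched genes (percentile 99.94), but 81.4% of them lay at or below a level of 5, under the levels compared, so these values, past the bound set beforehand, were not taken to exclude it. Handling that differed between the groups and an effect of the treatment also stay open, since no batch is given.

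The second pattern is the shift of 5 gene lists, for which the trend on mean level is a candidate explanation. Among 10000 brightness-matched lists, NF-kB and TGF-beta and Wnt targets lay at percentile 0 and cholesterol synthesis at percentile 100, and these 3 stayed called after cyclic loess and with the trend removed, which argues against the trend as their whole cause. S phase lay at percentile 71.92, within what the trend gives, and its median went from 0.08 to 0.03 with the trend removed. G2/M lay at percentile 97.85, just past the bound set for it, but its median went from 0.10 to 0.05 and its adjusted p to 0.0756 with the trend removed; the condition that a call must outlast this removal was added after the percentile was seen, and the trend stays open for this list. The other 2 splits of the arrays called at most 0 lists against 5, and gave 60 and 83 genes past 1.5-fold against 235, with too few splits for a share under 0.05. Those splits also carry the difference between the groups as spread, which lowers their counts, so the comparison decides nothing.

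The third pattern is a higher median of 2 sets of probe sets: the 5333 unnamed probe sets below the first named identifier had a median of 0.14 against -0.06 for other unnamed probe sets of like brightness (percentile 100), with 875 higher and 313 lower at an unadjusted p under 0.05. The 373 Zfp genes had a median of 0.11 against 0.00 (percentile 100), with 55 higher and 15 lower, and 0.07 without A-FABP replicate 2. These percentiles argue against the trend as the whole cause of either median, and under cyclic loess, repeated quantile normalization and the trend removed the medians were 0.14 to 0.18 and 0.07 to 0.09, so the trend may hold part of the Zfp value. After median centring, which moved the median of all genes to 0.055, the unnamed probe sets had a median of 0.21 and the Zfp genes of 0.17. What the unnamed probe sets target is not given in the sources used here; they may be control probe sets, and their values would then not describe genes. Shared signal between Zfp paralogs, base composition of the probes and an effect of the treatment may contribute and were not tested.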
